A study of Mus musculus with 14 samples.

How the data were processed

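Poly(A) RNA of 14 mouse tumour samples was sequenced, and 1 table of gene counts for all libraries was deposited. Per the submitters' processing notes, the authors estimated expression with RSEM 1.3.1, which assigns reads to transcripts and gives an expected count per gene. The aligner, the genome build, the annotation and any use of strand are not given in the sources used here, so no coordinates are reported. The deposited estimated counts were whole numbers already, so the rounding planned for expected counts changed none of them. The table held 14979 gene symbols, each with a mean above 20 counts over the 14 libraries (lowest mean 20.07), so genes below that level were not analysed here. Symbols carried the changes that R makes to names. Of these, 14240 matched a mouse gene symbol as written, 395 matched after these changes were undone, and 344 were used as written without a match. An estimated count can divide reads between near-identical genes, so values of Tgtp1 and Tgtp2, of the globin gene pairs and of Ly6c1 and its copy are uncertain one by one. Each column was tied to its sample through the column name given in that sample's description, and each sample to its group through its title. The titles number the replicates.

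Library totals ranged from 59 to 78.5 M counts and set the precision of single values. At this depth the spread between samples exceeded counting noise by far. The lowest chi-square per degree of freedom between 2 libraries of 1 group was 96. Their Spearman correlations across genes lay between 0.937 and 0.991, so no 2 libraries held the same counts. This does not show that they came from different tumours, and each was used as 1 sample, as labelled.

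Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust estimation, TMM scaling and the filterByExpr filter, which removed 22 genes holding 0.0034% of counts and left 14957. All 14 libraries entered 1 fit with the group as the only factor, so the groups shared 1 estimate of the spread (common biological coefficient of variation 0.367). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose", "fell" and "passed" refer to that call, for genes and for lists. SE was the absolute log2 fold change divided by the square root of the test's F statistic. CPM values used the TMM-scaled library sizes. The 7 comparisons were each treatment against PBS and the full combination against each combination lacking 1 component.

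Gene lists were fixed before the data were examined, as were the groups, the tests, the checks with other settings and the rule for named genes. The 30 lists covered T cells, cytotoxic effectors, natural killer cells, T cell inhibitory receptors, regulatory T cells, B and plasma cells, lymphoid tissue chemokines, macrophages and monocytes, suppressive myeloid cells, neutrophils, dendritic cells, and eosinophils, mast cells and basophils. They also covered interferon gamma and type I interferon responses, MHC class I and class II presentation, nucleic acid sensing, p53 and DNA damage, hypoxia and glycolysis, immediate early and heat shock genes, proliferation and mitochondrially encoded genes. Melanocyte, squamous, cornified epidermis, fibroblast, endothelial, skeletal muscle, adipocyte and red blood cell lists described the tumour lineage and other tissue. Of the symbols they named, 468 were in the deposited table, 19 of them in more than 1 list. Symbols absent from it were not analysed, which left 6 of 20 B and plasma cell symbols and 8 of 20 melanocyte symbols. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison. Camera with an estimated correlation, and fry, which asks only whether a list's genes move 1 way, were run beside it. No list in any of the 7 comparisons was called with an estimated correlation. A list level is the mean log2 CPM of its members in a library.

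Named genes followed a fixed rule. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap in CPM and whose mean was at least 1 CPM, leaving out predicted genes and immune receptor segments, or the 5 smallest p where fewer than 5 genes qualified. To these it added 26 fixed genes, of which 23 were tested, up to 4 genes with the smallest p from each list that passed, and up to 5 lineage genes of highest mean CPM. Genes outside this rule are named as such where they appear, except list members and keratins quoted for the level of a library or group.

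The results were repeated with RLE scaling, DESeq2 1.42.0, limma-voom, no count filter, a stricter filter of 2 CPM in at least 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, 2 further fits were added, namely removal of each library's trend on transcript length and GC content, and a T cell and natural killer cell level as a covariate. Lengths and GC contents came from GENCODE mouse transcripts and covered 95.9% of tested genes.

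The steps were tested on simulated counts for the 14957 genes. For TRT_ISV_DCP against PBS, edgeR recovered 36% of 100 genes changed by 1 log2 unit and 69% of 100 changed by 2, with 7 false calls among 115. For TRT_ISV against PBS the shares were 25% and 64%, with 5 false calls among 99. The planted list was recovered in both simulations, and 0 of the 30 other lists were called. Simulated genes varied independently of each other, whereas genes of a real list moved together. The estimated correlation was 0.602 for T cell genes in TRT_ISV_DCP against PBS. The simulation therefore cannot show how often camera calls an unchanged list in these data.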

Results

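Gene expression was measured by poly(A) RNA sequencing in 14 mouse tumour samples from 5 treatment groups. The PBS, TRT_DCP, ISV_DCP and TRT_ISV_DCP groups held 3 libraries each, and the TRT_ISV group held 2. TRT stands for targeted radionuclide therapy, here an intravenous 20 µCi dose of yttrium-labelled NM600, a beta-emitting agent that accumulates in tumours. The protocol estimates a mean tumour dose of 2.5 Gy. ISV stands for in situ vaccine, which the protocol describes as external beam radiation of 8 Gy to the right flank tumour followed by injection of cetuximab and interleukin 2 into that tumour. DCP is dual checkpoint blockade, with antibodies against PD-L1 and CTLA-4. Per the protocol, the sequenced tumours came from the left flank, outside the beam and the injections, and were collected on day 12. The sample labels give week 3 instead. The protocol text is the same for every sample, so it does not say which groups received the beam. Library totals ranged from 59 to 78.5 M counts, and group means from 66 M in TRT_ISV_DCP to 75.4 M in TRT_ISV. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Values below are CPM (counts scaled to library size), given as mean ± SD, and log2 fold changes (log2FC) with standard errors (SE).

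The labels disagree on the tumour cells. Sample labels name B78, a mouse melanoma line, while the design text and protocol describe MOC2, a mouse oral squamous carcinoma line whose unmodified cells were grafted into the left flank. Keratin 8 and keratin 18, filaments of simple and many malignant epithelia, averaged 739 CPM (Krt8, range 421 to 1260) and 172 CPM (Krt18, range 43.7 to 375) over the 14 libraries. The integrin Itgb4 and Krt19 averaged 198 and 161 CPM. Markers of basal squamous cells in the same list were nearly absent in most libraries, with medians of 0.00615 CPM for Krt5, 0.267 for the transcription factor gene Trp63 and 0.278 for the desmosome gene Dsp. Among melanocyte genes, the melanosome matrix gene Pmel averaged 0.594 CPM and lay between 0.402 and 0.952 CPM, while Gpnmb, which macrophages also express, averaged 50.5 CPM. The melanocyte regulators Mitf and Pax3 averaged 12.6 and 10.8 CPM, and the receptor gene Kit 5.35 CPM. Tyr, Dct, Mlana and Sox10 were absent from the deposited counts, which held only genes with a mean above 20 counts, and were not analysed here.

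**Figure D1:**
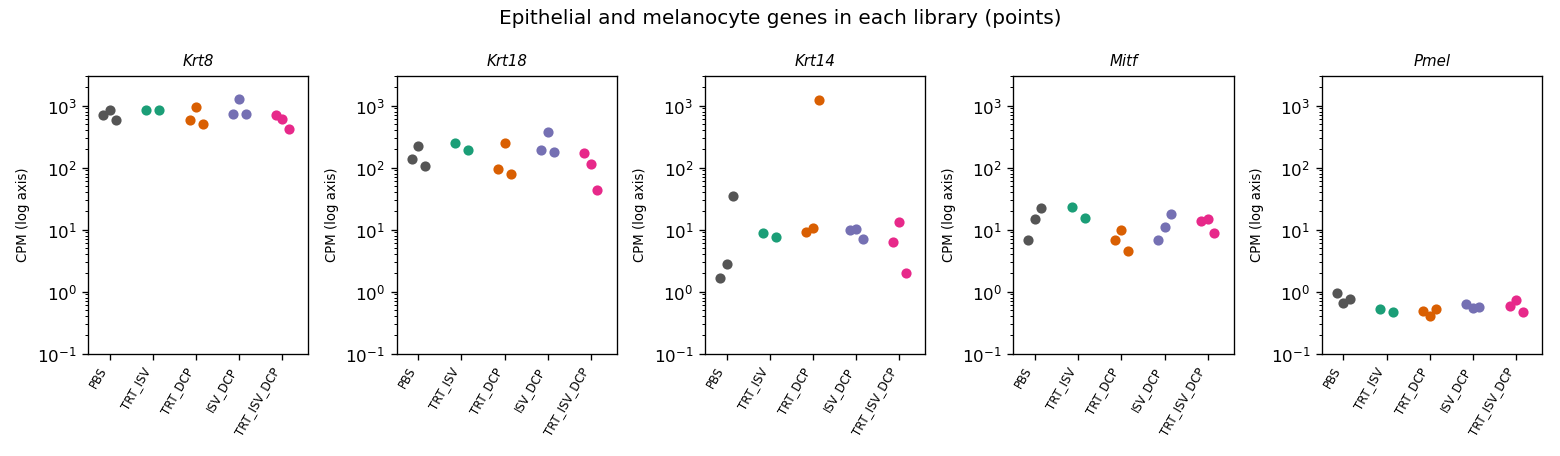
CPM (log axis) of 3 keratin genes and of 2 melanocyte genes in each library (points), by treatment group. Krt8 lay between 421 and 1260 CPM and Pmel between 0.402 and 0.952 CPM in all 14 libraries, and Krt14 reached 1220 CPM in 1 TRT_DCP library.

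The full combination, TRT_ISV_DCP, was first compared with PBS (3 libraries each), which asks what the 3 treatments together go with in a tumour that was neither irradiated by the beam nor injected. Interferon gamma response genes rose most broadly. The chemokine Cxcl9, which attracts activated T cells, went from 0.547 ± 0.286 to 19 ± 5.42 CPM (SD, n = 3, log2FC 5.12, SE 1.27, edgeR adjusted p = 0.0452). The interferon-induced GTPase genes Tgtp2 (4.24 to 104.9 CPM, log2FC 4.63, SE 0.73) and Iigp1 (12.4 to 190.8 CPM, log2FC 3.95, SE 0.64) rose as well. Lower were glycolytic and hypoxia genes, with Gapdh falling from 10610 ± 3819 to 3906 ± 389 CPM (log2FC -1.44, SE 0.27). The neutrophil granule genes Ngp (log2FC -6.08, SE 1.11) and Camp (log2FC -4.65, SE 1.05) fell too. They were the only 2 of 17 neutrophil genes to fall (6 adjusted over the list alone), and 7 of the 17 were higher. The neutrophil list fell (median log2FC -1.60, camera adjusted p = 0.00971, adjusted p = 0.446 with an estimated correlation), a call lost without TRT_ISV_DCP replicate 1 (0.183).

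Of the 24 interferon gamma genes tested in TRT_ISV_DCP against PBS, 15 rose, none fell and 9 did not pass. Adjusted over the list alone, 20 of the 24 rose. The list's median log2FC was 2.63 (camera adjusted p = 2.53e-21, adjusted p = 0.318 with an estimated correlation). In the MHC class I list, which covers peptide processing and display to CD8 T cells, 6 of 19 genes rose (14 adjusted over the list alone, camera adjusted p = 1.02e-09, adjusted p = 0.318 with an estimated correlation). Among them were H2-Q7 (log2FC 3.49, SE 0.68), the immunoproteasome subunit Psmb9 (log2FC 2.91, SE 0.60) and Nlrc5, the transactivator of class I genes (8.26 ± 5.3 to 88.3 ± 11.7 CPM). T cell genes had a median log2FC of 3.28, with all 18 higher. Only Thy1, which is also in the fibroblast list, and the costimulatory receptor Cd28 passed over all genes. When adjusted over the T cell list alone 15 passed (camera adjusted p = 3.32e-09, adjusted p = 0.318 with an estimated correlation). Cd8a was 0.29 ± 0.162 CPM in PBS and 8 ± 6.23 CPM in TRT_ISV_DCP and missed the threshold (edgeR adjusted p = 0.0562). Cytotoxic effector genes, such as granzyme B (Gzmb, 8.37 ± 9.04 against 92.7 ± 20.5 CPM) and perforin (Prf1, 7.56 ± 8.34 against 70.1 ± 2.46 CPM), passed as a list (median log2FC 2.79, camera adjusted p = 8.23e-07, adjusted p = 0.335 with an estimated correlation). None of its 19 genes passed over all genes, and 9 did when adjusted over the list alone.

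In the same comparison 4 of 14 genes of cytosolic and endosomal nucleic acid sensing rose (6 adjusted over the list alone), including the RNA sensor Tlr3 (log2FC 1.60, SE 0.28) and the DNA sensor Tlr9 (log2FC 3.36, SE 0.71). The list's camera adjusted p was 8.35e-06, with adjusted p = 0.318 under an estimated correlation. The endothelial genes Kdr and Tie1, receptors of blood vessel cells, rose by 1.64 and 1.27 on the log2 scale (2 of 20 in the list, 9 adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.318 with an estimated correlation). Natural killer cell genes (median log2FC 2.21; 0 of 12 passed over all genes or adjusted over the list alone, camera adjusted p = 0.000327) and macrophage genes (1.35; 1 rose and 1 fell of 20, and 4 and 1 adjusted over the list alone; 1.22e-05) also rose as lists, with adjusted p = 0.369 and 0.335 under an estimated correlation. The macrophage list level was 2.34, 4.54 and 3.04 log2 CPM in PBS and 4.45, 4.9 and 5.32 in TRT_ISV_DCP, so PBS replicate 2 lay above TRT_ISV_DCP replicate 1. The macrophage fractalkine receptor Cx3cr1 rose by 4.42 (SE 0.98) and the efferocytosis receptor Mertk fell by 0.77 (SE 0.17) on the log2 scale. Of the 24 hypoxia and glycolysis genes, 8 fell and none rose (16 adjusted over the list alone, median log2FC -0.91, camera adjusted p = 6.98e-12, adjusted p = 0.318 with an estimated correlation), among them Higd1a, Bnip3l and Mif. The 9 red blood cell genes were all lower (median log2FC -3.53), none passing over all genes and 9 when adjusted over the list alone (camera adjusted p = 6.15e-06, adjusted p = 0.318 with an estimated correlation). Globin genes took 0.842%, 0.103% and 1.78% of counts in PBS replicates 1, 2 and 3 and at most 0.0711% in the TRT_ISV_DCP libraries. Skeletal muscle genes, which can come from body wall muscle, were also higher in this group (median log2FC 3.01, 0 of 17 called and 11 adjusted over the list alone, camera adjusted p = 9.27e-05, adjusted p = 0.369 with an estimated correlation). Their mean level was 2.89, 5.77 and 2.45 log2 CPM in the 3 TRT_ISV_DCP libraries and 0.21, 2.48 and 0.86 in the PBS libraries. Proliferation genes were higher in 28 of 30 cases (median log2FC 0.66, none passing over all genes or adjusted over the list alone, camera adjusted p = 2.53e-05, adjusted p = 0.446 with an estimated correlation). Their level was 4.78, 6.46 and 5.22 log2 CPM in PBS and 6.22, 6.17 and 6.54 in TRT_ISV_DCP. PBS replicate 2 thus lay above TRT_ISV_DCP replicates 1 and 2. Squamous epithelium genes were lower in 23 of 27 cases (median log2FC -0.96, none passing either way, camera adjusted p = 0.00286, adjusted p = 0.446 with an estimated correlation). Their level was 1.76, 1.61 and 3.29 log2 CPM in PBS and 1.47, 2.38 and 0.74 in TRT_ISV_DCP. TRT_ISV_DCP replicate 2 thus lay above PBS replicates 1 and 2. The immediate early and heat shock list fell as well (3 of 21 fell, 6 lower and 1 higher adjusted over the list alone, median log2FC -0.54, camera adjusted p = 0.00138, adjusted p = 0.369 with an estimated correlation). Its level was 6.69, 5.92 and 7.18 log2 CPM in PBS and 6.1, 6.02 and 6.03 in TRT_ISV_DCP. PBS replicate 2 thus lay below every TRT_ISV_DCP library, and the fall rested on PBS replicates 1 and 3.

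In all, 727 of 14957 genes passed in TRT_ISV_DCP against PBS by edgeR (336 rose and 391 fell), and the 2 groups did not overlap in 30.4% of genes, against 10% by chance. The gene count rested on single libraries. It was 2 without PBS replicate 1 or TRT_ISV_DCP replicate 1, 0 without PBS replicate 3 or TRT_ISV_DCP replicate 2 or 3, and 3582 without PBS replicate 2. None of the 48 named genes called here passed in every one of those fits. Other tools also differed, with 2757 genes by DESeq2, 275 by limma-voom and 7 in a fit of these 2 groups alone. Apart from the neutrophil list, the lists named above held whichever library was left out. Other lists that rose here did not. Without 1 library the highest camera adjusted p was 0.0771 for type I interferon, 0.103 for B cell and 0.0678 for dendritic cell genes. It was 0.0909 for eosinophil, mast cell and basophil, 0.116 for fibroblast, 0.191 for MHC class II and 0.974 for mitochondrially encoded genes.

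**Figure D2:**
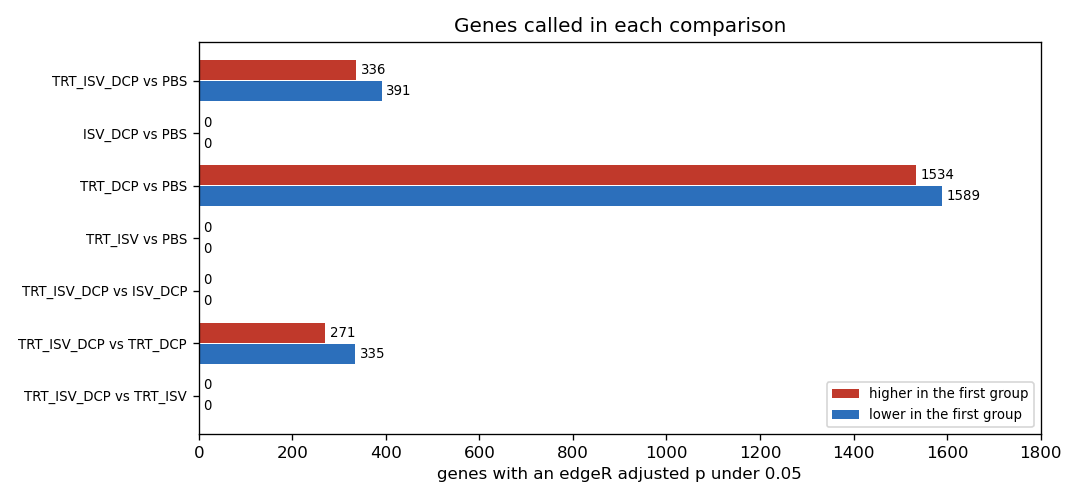
Number of genes with an edgeR adjusted p under 0.05 in each of the 7 comparisons. Red bars count genes higher in the first group and blue bars genes lower in it. The counts were 336 and 391 for TRT_ISV_DCP against PBS, 1534 and 1589 for TRT_DCP against PBS, 271 and 335 for TRT_ISV_DCP against TRT_DCP, and 0 elsewhere.

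TRT_DCP, the combination without the vaccine, was compared with PBS (3 libraries each). Antigen presentation, interferon gamma, macrophage and lymphocyte lists were higher in this group, but all except the macrophage list mainly in 2 of its 3 libraries. Cx3cr1 rose from 0.128 ± 0.085 to 19.1 ± 2.74 CPM (SD, n = 3, log2FC 7.19, SE 1.08, edgeR adjusted p = 0.00852). Cd4, the coreceptor of helper T cells, rose from 0.94 ± 0.761 to 10 ± 4.95 CPM (log2FC 3.41, SE 0.63), and Cxcl10 from 3.99 ± 1.52 to 53 ± 38.9 CPM (log2FC 3.73, SE 0.64). The hypoxia genes Egln3 (186.6 to 33.3 CPM) and Ndrg1 (828 to 191.5 CPM) fell by 2.48 and 2.11 on the log2 scale.

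MHC class II genes, which display peptides to CD4 T cells, rose in 8 of 10 cases in TRT_DCP against PBS (10 adjusted over the list alone, median log2FC 3.55, camera adjusted p = 3.69e-06, adjusted p = 0.348 with an estimated correlation). The class II lysosomal reductase gene Ifi30 rose from 26.8 ± 19.6 to 145.3 ± 47.1 CPM (log2FC 2.44, SE 0.49), whereas H2-Ab1, although called (log2FC 4.38, SE 1.25), overlapped between groups and lost its call without PBS replicate 1 or 3 or TRT_DCP replicate 3. Interferon gamma genes rose in 17 of 24 cases (20 adjusted over the list alone, median log2FC 2.44, camera adjusted p = 2.49e-11, adjusted p = 0.348 with an estimated correlation), led by Cxcl9 (log2FC 6.38, SE 1.34). The type I interferon list (3 of 27 rose, 1 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.729 with an estimated correlation) was high in TRT_DCP replicate 1 only, at 6.15 log2 CPM against 4.67 and 4.58 in the other 2 and 4.78, 3.47 and 5.12 in PBS. Its call was lost without that library (0.813) or PBS replicate 2 (0.816). For MHC class I, 11 of 19 genes rose (17 adjusted over the list alone, camera adjusted p = 1.05e-08, adjusted p = 0.348 with an estimated correlation), including Psmb9, Psmb10, Psme2 and H2-Q7. In the macrophage and monocyte list 12 genes rose and 1 fell of 20 (16 and 1 adjusted over the list alone, camera adjusted p = 3.13e-07, adjusted p = 0.348 with an estimated correlation). The complement gene C1qa rose from 56.9 ± 60.3 to 402.6 ± 82.8 CPM, and Mertk fell by 0.98 (SE 0.17) on the log2 scale. T cell genes rose in 8 of 18 cases (13 adjusted over the list alone, camera adjusted p = 5.03e-05, adjusted p = 0.449 with an estimated correlation). Cd8a rose from 0.29 ± 0.162 to 4.55 ± 4.27 CPM, but the groups overlapped and its call was lost without any one of 5 of the 6 libraries, the exception being TRT_DCP replicate 2. That library lay close to PBS in several lists. Its MHC class I level was 6.47 log2 CPM (PBS at most 6.36), its MHC class II level 3.32 (at most 3.29) and its interferon gamma level 2.99 (at most 2.72). Its T cell level was -0.92 log2 CPM, against 1.88 and 1.21 in TRT_DCP replicates 1 and 3 and -1.57, -1.67 and -1.13 in PBS, and its B cell level -0.81, against 1.66 and 1.45 and at most -1.23. The B cell genes Cd22 (log2FC 2.70, SE 0.41) and Cd79b (3.40, SE 0.67) rose among 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.00372, adjusted p = 0.384 with an estimated correlation). Dendritic cell genes rose in 2 of 11 cases, the costimulatory genes Cd40 and Cd86 (4 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.348 with an estimated correlation).

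In this comparison 17 of 24 hypoxia and glycolysis genes fell and none rose over all genes (21 fell and 1 rose adjusted over the list alone, median log2FC -1.07, camera adjusted p = 2.01e-13, adjusted p = 0.348 with an estimated correlation). Red blood cell genes fell in 7 of 9 cases, also 7 adjusted over the list alone (median log2FC -5.98, camera adjusted p = 4.63e-05, adjusted p = 0.348 with an estimated correlation). Hba-a1 and Hba-a2 share reads, so their separate values are uncertain. Mitochondrially encoded genes were higher (4 of 13 rose, 6 adjusted over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.433 with an estimated correlation). In the p53 and DNA damage list 7 genes fell and 1 rose of 28 (7 and 2 adjusted over the list alone, median log2FC -0.32, camera adjusted p = 0.0395, adjusted p = 0.348 with an estimated correlation). The p53 targets Cdkn1a and Mdm2 fell by 1.57 (SE 0.42) and 0.75 (SE 0.17) on the log2 scale. The Cdkn1a call was lost without any one of PBS replicates 1 and 3 and TRT_DCP replicates 1 and 2 (log2FC -0.89 without PBS replicate 3), and the Mdm2 call without PBS replicate 3. The list's call was lost without PBS replicate 3 (adjusted p = 0.0795) or TRT_DCP replicate 2 (0.112). Another library stood apart. TRT_DCP replicate 3 held 545 CPM of Krt5 and 1220 CPM of Krt14, keratins of basal skin and squamous epithelium. Its squamous list level was 6.06 log2 CPM, against 0.86 and 1.36 in the other 2 libraries of its group. It also had the highest MHC class II level, 6.55 against 4.89 and 3.32 log2 CPM, and an interferon gamma level of 5.86 against 5.03 and 2.99.

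By edgeR 3123 of 14957 genes passed in TRT_DCP against PBS (1534 rose and 1589 fell), and 31% of genes did not overlap between groups, against 10% by chance. With any single library left out, 31 of the 78 named genes called here still passed, including Cx3cr1, Cd4, Cxcl9, Cxcl10, Egln3 and Ndrg1. The count was 1278 without PBS replicate 1, 4756 without PBS replicate 2, 861 without PBS replicate 3, 1289 without TRT_DCP replicate 1, 3333 without TRT_DCP replicate 3 and 0 when these 2 groups were fitted alone.

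**Figure D3:**
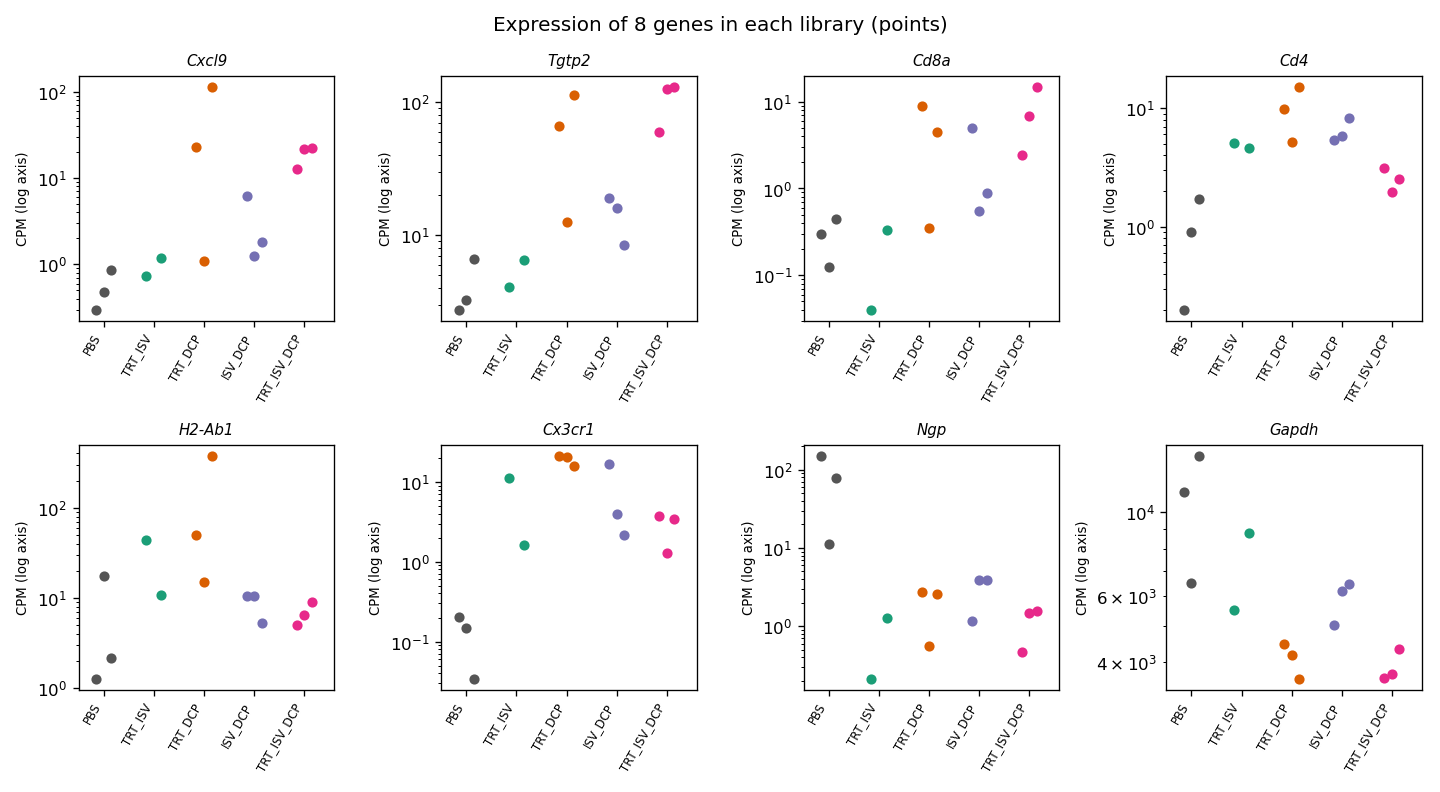
CPM (log axis) of 8 genes in each library (points), by treatment group. Cx3cr1 lay under 0.21 CPM in the 3 PBS libraries and over 15 CPM in the 3 TRT_DCP libraries, and Gapdh averaged 10610 CPM in PBS and 3906 CPM in TRT_ISV_DCP.

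ISV_DCP, the combination without the radionuclide, was compared with PBS (3 libraries each). T cell, macrophage and interferon gamma genes were higher as lists, with no single gene past the threshold. Cx3cr1 was 0.128 ± 0.085 CPM in PBS and 7.6 ± 7.88 CPM in ISV_DCP (SD, n = 3, log2FC 5.86, SE 1.03, edgeR adjusted p = 0.188), and Cd4 0.94 ± 0.761 and 6.5 ± 1.57 CPM (log2FC 2.79, SE 0.62, adjusted p = 0.188). The smallest adjusted p, 0.0752, belonged to Grb14, an adaptor of receptor tyrosine kinases (2.49 ± 0.534 against 10.8 ± 2.79 CPM).

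The T cell list had a median log2FC of 2.16 in ISV_DCP against PBS with 17 of 18 genes higher (2 adjusted over the list alone, camera adjusted p = 6.74e-05). ISV_DCP replicate 1 stood apart, with a T cell level of 1.23 log2 CPM against -0.86 and -0.78 in the other 2 libraries of its group and -1.57, -1.67 and -1.13 in PBS. Macrophage and monocyte genes were higher in 17 of 20 cases (median 1.20; 1 higher and 1 lower adjusted over the list alone; 1.49e-05) and interferon gamma genes in 22 of 24 (median 0.71; 0 adjusted over the list alone; 1.49e-05). The macrophage level was 5.02, 4.55 and 4.38 log2 CPM in ISV_DCP and 2.34, 4.54 and 3.04 in PBS. PBS replicate 2 thus lay within the range of ISV_DCP. Fibroblast and matrix genes, such as Col1a1 (345.7 ± 224 against 1047 ± 294 CPM), had a camera adjusted p of 0.00418 (2 of 20 adjusted over the list alone). Red blood cell genes were lower in 9 of 9 cases (median -2.37; 0 adjusted over the list alone, camera adjusted p = 0.000368). Adjusted p = 0.463 was obtained for each of these 5 lists with an estimated correlation. Muscle genes were lower in 17 of 17 cases (median -1.93; 0 adjusted over the list alone, camera adjusted p = 5.18e-05, adjusted p = 0.463 with an estimated correlation), a call lost without PBS replicate 2 (adjusted p = 0.053), whose muscle level of 2.48 log2 CPM was the highest of the PBS libraries.

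edgeR called 0 genes in ISV_DCP against PBS, with 2304 at an unadjusted p under 0.05. limma-voom also called 0, and DESeq2 602. Without PBS replicate 2 edgeR called 1360.

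TRT_ISV, which had no checkpoint antibodies and only 2 libraries, was compared with PBS (3 libraries). Neutrophil genes were lower in 16 of 17 cases. S100a8, an abundant neutrophil calcium-binding protein gene, was 120.2 ± 71.1 CPM in PBS and 9.09 ± 3.61 CPM in TRT_ISV (log2FC -3.72, SE 0.80, edgeR adjusted p = 0.244). Lcn2, a neutrophil granule protein gene, was 47.6 ± 33.2 and 2.87 ± 1.63 CPM. The mast cell protease gene Mcpt2 was 0.03 ± 0.027 CPM in PBS and 15.8 ± 7.15 CPM in TRT_ISV (adjusted p = 0.168), and the tryptase gene Tpsb2 1.64 ± 1.55 and 27.9 ± 5.53 CPM (0.386). T cell and interferon gamma genes did not pass as lists, with median log2FC -0.30 (camera adjusted p = 0.827; 0 of 18 passed over all genes or adjusted over the list alone) and 0.03 (0.399; 0 of 24 either way).

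Of the 17 neutrophil genes, 16 were lower in TRT_ISV than in PBS and 14 passed when adjusted over the list alone, none over all genes (median log2FC -3.41, camera adjusted p = 2.97e-21, adjusted p = 0.206 with an estimated correlation). The eosinophil, mast cell and basophil list was higher in 9 of 12 genes (3 adjusted over the list alone, median 2.56, camera adjusted p = 7.28e-05, adjusted p = 0.339 with an estimated correlation). Red blood cell genes were lower in 9 of 9 cases (7 adjusted over the list alone, median -5.18, camera adjusted p = 2.25e-07, adjusted p = 0.339 with an estimated correlation). MHC class II genes were higher in 10 of 10 cases (0 adjusted over the list alone, median 1.34, camera adjusted p = 9.54e-05, adjusted p = 0.737 with an estimated correlation). Their level was 4.1 and 2.55 log2 CPM in TRT_ISV and 0.11, 3.29 and 0.57 in PBS, so PBS replicate 2 lay above TRT_ISV replicate 2. The MHC class II list lost its call without TRT_ISV replicate 1. Fibroblast genes (median 0.78, 14 of 20 higher, 0 adjusted over the list alone, camera adjusted p = 0.00916, adjusted p = 0.676 with an estimated correlation) lost theirs without TRT_ISV replicate 1 (0.191) or PBS replicate 1 (0.0583). Ribosomal 18S RNA took 0.318% and 0.385% of counts in the 2 TRT_ISV libraries and 0.109% to 0.19% in PBS.

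edgeR called 0 genes in TRT_ISV against PBS, with 1531 at an unadjusted p under 0.05. limma-voom called 0 and DESeq2 248. Without PBS replicate 2 edgeR called 261, and in fits without 1 TRT_ISV library the remaining one is assumed to vary like the other groups.

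**Figure D4:**
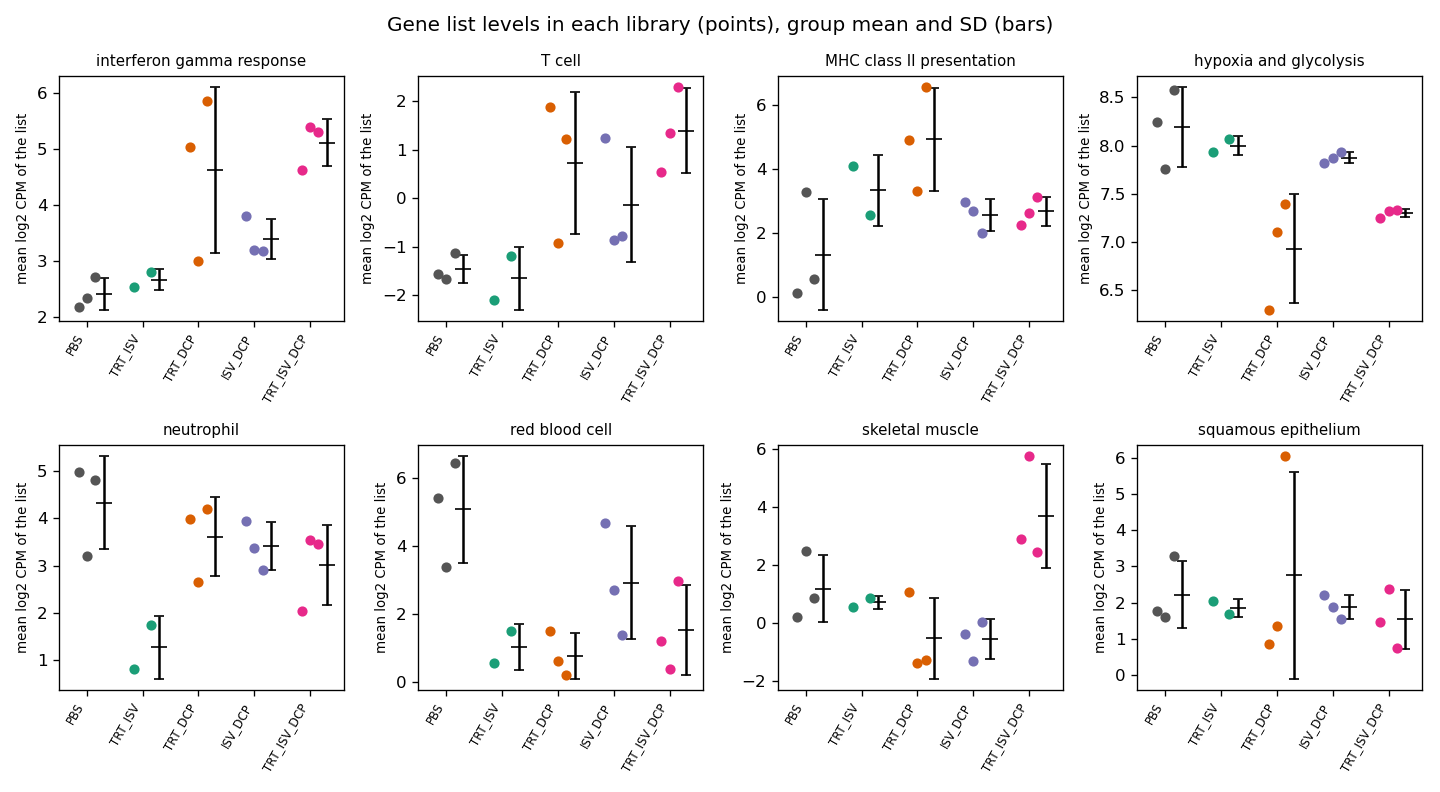
Mean log2 CPM of 8 gene lists in each library (points), with the mean and SD of each treatment group (bars beside the points). The interferon gamma level averaged 2.41 in PBS, 2.66 in TRT_ISV, 3.39 in ISV_DCP, 4.63 in TRT_DCP and 5.11 in TRT_ISV_DCP, and the neutrophil level was lowest in TRT_ISV at 1.28.

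Adding the radionuclide was examined by comparing TRT_ISV_DCP with ISV_DCP (3 libraries each). Interferon gamma response genes were higher with the radionuclide. Iigp1 was 26.7 ± 8.75 CPM in ISV_DCP and 190.8 ± 65.2 CPM in TRT_ISV_DCP (SD, n = 3, log2FC 2.84, SE 0.61), and Tgtp2 14.5 ± 5.44 and 104.9 ± 39.2 CPM (log2FC 2.85, SE 0.67), each with an edgeR adjusted p of 0.597. Glycolysis genes were lower, as for the glucose transporter Slc2a1 (588.3 ± 15.8 against 253.2 ± 32.1 CPM) and hexokinase Hk2 (221.8 ± 16.4 against 107.8 ± 24.6 CPM). Cd8a was 2.12 ± 2.44 and 8 ± 6.23 CPM, while Cd4 was 6.5 ± 1.57 in ISV_DCP and 2.55 ± 0.575 CPM in TRT_ISV_DCP, and neither passed (adjusted p = 0.987 for both).

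Of 24 interferon gamma genes, 23 were higher in TRT_ISV_DCP than in ISV_DCP and 16 passed when adjusted over the list alone, none over all genes (median log2FC 1.62, camera adjusted p = 3.67e-33, adjusted p = 0.113 with an estimated correlation). MHC class I genes were higher in 18 of 19 cases (median 0.79, 2.91e-12, adjusted p = 0.206 with an estimated correlation), T cell genes in 17 of 18 (median 1.70, 2.14e-08, adjusted p = 0.313 likewise) and type I interferon genes in 26 of 27 (median 0.58, 5.58e-07, adjusted p = 0.439 likewise). None of these passed when adjusted over the list alone. Hypoxia and glycolysis genes were lower in 24 of 24 cases (median -0.55, camera adjusted p = 3.72e-15, adjusted p = 0.189 with an estimated correlation), and immediate early and heat shock genes, such as Fos and the chaperone Hspa1a, in 19 of 21 (median -0.57, 2.91e-12, adjusted p = 0.121 with an estimated correlation). In both lists 0 passed adjusted over the list alone. Skeletal muscle genes were higher in 16 of 17 cases, 16 of them adjusted over the list alone (median 5.17, camera adjusted p = 2.28e-31, adjusted p = 0.113 with an estimated correlation), and adipocyte genes in 9 of 10 (2 adjusted over the list alone, camera adjusted p = 5.67e-05, adjusted p = 0.121 with an estimated correlation). Muscle levels were 2.89, 5.77 and 2.45 log2 CPM in the TRT_ISV_DCP libraries and -0.39, -1.32 and 0.02 in ISV_DCP.

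edgeR called 0 genes in TRT_ISV_DCP against ISV_DCP, with 693 of 14957 at an unadjusted p under 0.05 and a smallest adjusted p of 0.597. Those 693 are no more than the share of 0.05 that chance alone would give. The 2 groups did not overlap in 15.8% of genes, against 10% by chance. limma-voom called 0 and DESeq2 72. The lists named above passed whichever library was left out. Other called lists did not, among them natural killer cell, endothelial, proliferation, red blood cell and squamous genes. Their highest camera adjusted p without 1 library was 0.197, 0.245, 0.832, 0.157 and 0.282.

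Adding the vaccine was examined by comparing TRT_ISV_DCP with TRT_DCP (3 libraries each). The genes that rose most were those of skeletal muscle fibres, such as the calcium pump Atp2a1 (0.609 ± 0.904 to 116.9 ± 172.5 CPM, SD, n = 3, log2FC 7.57, SE 1.76, edgeR adjusted p = 0.0421) and the giant sarcomere gene Ttn (2.84 ± 1.06 to 40 ± 44 CPM, log2FC 3.81, SE 0.82). These rises rested largely on TRT_ISV_DCP replicate 2, which held 316 CPM of Atp2a1, against 18.9 and 15.8 CPM in replicates 1 and 3, and a muscle level of 5.77 log2 CPM, against 2.89 and 2.45. Without it the log2FC was 4.83 for Atp2a1 and 2.37 for Ttn, and both calls were lost without any one of the 6 libraries. Among the genes that fell, Tyrobp, a signalling adaptor of myeloid and natural killer cells, went from 113.7 ± 24.9 to 46.3 ± 11.4 CPM (log2FC -1.29, SE 0.29), and the class II chaperone gene H2-DMa from 20.1 ± 13.8 to 4.98 ± 1.29 CPM (log2FC -2.01, SE 0.49). S100a4, a calcium-binding protein gene of motile and mesenchymal cells, fell from 976 ± 57.3 to 346.2 ± 158.4 CPM. Cd4 was 10 ± 4.95 CPM in TRT_DCP and 2.55 ± 0.575 CPM in TRT_ISV_DCP and missed the threshold (adjusted p = 0.0754). Prf1 was 7.82 ± 7.51 and 70.1 ± 2.46 CPM and did not pass either (adjusted p = 0.156).

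In this comparison 5 of 17 muscle genes rose (16 adjusted over the list alone, median log2FC 4.56, camera adjusted p = 5.83e-11, adjusted p = 0.889 with an estimated correlation). All 10 MHC class II genes were lower and 1 fell (8 adjusted over the list alone, median -2.55, camera adjusted p = 8.02e-05, adjusted p = 0.889 with an estimated correlation). The mitochondrially encoded list fell (median -0.53, 1 of 13 called and 3 adjusted over the list alone, camera adjusted p = 0.00281, adjusted p = 0.889 with an estimated correlation), a call lost without TRT_DCP replicate 3 (0.0502). The squamous epithelium list (median -3.24, 0 of 27 called either way, camera adjusted p = 0.0404, adjusted p = 0.889 with an estimated correlation) lost its call without that keratin-rich library (0.528) or without TRT_ISV_DCP replicate 3 (0.194). Neither interferon gamma (median 0.23, camera adjusted p = 0.194, 0 of 24 called or adjusted over the list alone) nor T cell genes (0.40, 0.329, 0 of 18 likewise) passed. Genes that rose had a median transcript length of 7047 nucleotides and genes that fell 1315 nucleotides, against 3318 in genes not called.

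edgeR called 606 genes (271 rose and 335 fell), and 29.1% of genes did not overlap between groups, against 10% by chance. None of the 21 named genes called here passed in every fit without 1 library. The count was 0 without TRT_DCP replicate 1 or 2 or TRT_ISV_DCP replicate 1 or 3, 397 without TRT_ISV_DCP replicate 2, and 1004 without TRT_DCP replicate 3. It was 1976 by DESeq2, 0 in a fit of these 2 groups alone and 0 once a trend on transcript length and GC content was removed from each library.

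Adding checkpoint blockade was examined by comparing TRT_ISV_DCP (3 libraries) with TRT_ISV (2 libraries). T cell, cytotoxic, interferon and neutrophil genes were all higher with the antibodies. Cd8a was 0.188 ± 0.209 CPM in TRT_ISV and 8 ± 6.23 CPM in TRT_ISV_DCP (log2FC 5.40, SE 1.63, edgeR adjusted p = 0.161), and Iigp1 10.4 ± 1.41 and 190.8 ± 65.2 CPM (log2FC 4.19, SE 0.78, adjusted p = 0.12). The interleukin 15 receptor gene Il15ra (2.27 ± 0.138 against 14.2 ± 3.72 CPM) and Ly6a, an interferon-inducible surface protein gene (101.7 ± 0.271 against 368.8 ± 61.8 CPM), were among the 5 genes with the smallest p, each at an adjusted p of 0.0815. The neutrophil collagenase gene Mmp8 was 2.33 ± 1.71 and 62.3 ± 39.5 CPM.

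No gene passed over all genes in TRT_ISV_DCP against TRT_ISV, but 18 of 24 interferon gamma genes did when adjusted over the list alone (median log2FC 2.21, camera adjusted p = 3.55e-19). So did 13 of 19 MHC class I genes (median 1.36, 6.32e-11), 14 of 18 T cell genes (median 3.39, 1.01e-09), 7 of 19 cytotoxic genes (median 2.88, 1.32e-08), 7 of 27 type I interferon genes (median 1.16, 6.46e-10) and 6 of 17 neutrophil genes (median 1.68, 1.06e-07). Hypoxia and glycolysis genes were lower in 23 of 24 cases (8 adjusted over the list alone, median -0.56, camera adjusted p = 6.31e-09). An estimated correlation gave adjusted p = 0.323 for each of these 7 lists. Proliferation genes were higher in 29 of 30 cases (median 0.94, 0 adjusted over the list alone, camera adjusted p = 2.82e-07, adjusted p = 0.463 with an estimated correlation). Muscle genes were higher here too, in 17 of 17 cases (11 adjusted over the list alone, median 3.82, camera adjusted p = 4.22e-07, adjusted p = 0.323 with an estimated correlation).

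edgeR called 0 genes in TRT_ISV_DCP against TRT_ISV, with 2812 at an unadjusted p under 0.05. limma-voom called 2, DESeq2 963 and an edgeR fit of these 2 groups alone 6. The 2 groups did not overlap in 54.5% of genes, against 20% by chance, and edgeR called 2 genes without TRT_ISV_DCP replicate 1.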

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

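The length and GC correction and the covariate fit were chosen after the results were seen, and all other settings beforehand. Counts of called genes changed little with RLE scaling and with either count filter in all 7 comparisons, and no called named gene changed sign. Over 615 gene results refitted in these ways, 7221 values stayed on the same side of the threshold, called or not, 774 lost a call, 302 gained one, 118 changed sign without being called and 0 did so while called. Scaling by RLE moved the median log2 fold change by at most 0.019. Depth, at 59 M counts or more, limited these results less than the spread between libraries. The cause of a moved count was not tested except where fewer libraries give it.

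DESeq2 called 2757 genes in TRT_ISV_DCP against PBS (727 by edgeR), 602 in ISV_DCP against PBS (0), 248 in TRT_ISV against PBS (0), 72 in TRT_ISV_DCP against ISV_DCP (0), 1976 against TRT_DCP (606) and 963 against TRT_ISV (0). limma-voom called 275 in TRT_ISV_DCP against PBS and 2 against TRT_ISV. A fit of only the 2 groups called 7 in TRT_ISV_DCP against PBS, 0 in TRT_DCP against PBS (3123), 0 in TRT_ISV_DCP against TRT_DCP and 6 against TRT_ISV. With the length and GC trend removed the counts were 1095 in TRT_ISV_DCP against PBS, 1 in ISV_DCP against PBS, 0 in TRT_ISV_DCP against TRT_DCP and 1 against TRT_ISV.

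As a replicate block, the number in the titles left 0 genes in TRT_ISV_DCP against PBS and 0 against TRT_DCP, gave 2488 in TRT_DCP against PBS and 0 elsewhere. The values do not show that the numbers pair the samples. Deviations of same-numbered libraries correlated between -0.357 and 0.293, over 0.1 in 8 of 26 pairs, against 14 of 52 pairs with different numbers. Of 14 libraries, 6 correlated best with their own number. With so few libraries per group, a pairing cannot be excluded either.

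Without 1 library, counts of genes ranged from 0 to 3582 in TRT_ISV_DCP against PBS, 0 to 1360 in ISV_DCP against PBS, 861 to 4756 in TRT_DCP against PBS, 0 to 261 in TRT_ISV against PBS, 0 to 1004 in TRT_ISV_DCP against TRT_DCP and 0 to 2 against TRT_ISV, and stayed 0 against ISV_DCP. The highest count came without PBS replicate 2 in the 4 comparisons with PBS, and without TRT_DCP replicate 3 and TRT_ISV_DCP replicate 1 in the last 2.

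Lists called by camera numbered 24, 21, 19 and 5 in TRT_ISV_DCP, ISV_DCP, TRT_DCP and TRT_ISV against PBS, and 16, 4 and 16 in TRT_ISV_DCP against ISV_DCP, TRT_DCP and TRT_ISV. With an estimated correlation 0 were called in each of the 7. fry called 11 in TRT_ISV_DCP against PBS, 13 in TRT_DCP against PBS and 0 in the other 5. Without the length and GC trend 9 lists were called in TRT_ISV_DCP against TRT_DCP. Leaving out 1 library gave 20 to 22, 12 to 21 (lowest without ISV_DCP replicate 1), 15 to 21 and 3 to 11 lists against PBS in the same order. In TRT_ISV against PBS the counts were 11 without PBS replicate 2, 3 without TRT_ISV replicate 1 and 9 without TRT_ISV replicate 2. For the full combination they were 14 to 18 against ISV_DCP, 4 to 10 against TRT_DCP (10 and 9 without TRT_DCP replicates 1 and 2, 9 and 7 without TRT_ISV_DCP replicates 1 and 3) and 14 to 18 against TRT_ISV.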

Other observations

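Tests chosen after their result was seen were the keratin test of the tumour lineage and its reading, the length test of TRT_ISV_DCP against TRT_DCP, the reading of the 2-group fit through its standard errors, the interval on the covariate test, the reading of the muscle test, and the choice below of Mcpt1, Per1, Per2 and Bmal1 and of the TRT_DCP values of Akr1c18, Ccn2 and Nr1d1. Further genes are given here one by one, not as groups. Mcpt1, a mucosal mast cell protease gene named after its values were seen, lay at 35.4 and 23.7 CPM in the 2 TRT_ISV libraries and between 0 and 4.98 CPM in the other 12, and did not pass in TRT_ISV against PBS (edgeR adjusted p = 0.244). Mcpt4, a connective tissue mast cell protease gene, averaged 17.2 ± 5.3 CPM in TRT_ISV and 1.14 ± 1.14 CPM in PBS and did not pass either (adjusted p = 0.419). Akr1c18, a steroid dehydrogenase gene, averaged 108.9 ± 25.1 CPM in PBS, 62.5 ± 17 in TRT_ISV, 44.1 ± 9.82 in ISV_DCP, 34.3 ± 7.13 in TRT_DCP and 15.9 ± 5.09 in TRT_ISV_DCP. It fell in TRT_ISV_DCP against PBS (log2FC -2.78, SE 0.29, adjusted p = 0.0125) and in TRT_DCP against PBS (log2FC -1.67, SE 0.28, adjusted p = 0.00986). Ccn2, a target of the YAP and TGF-beta pathways, fell in the same comparisons (log2FC -2.86, SE 0.53, and -3.01, SE 0.54). The clock repressor gene Nr1d1 fell in both as well, from 237 ± 207 CPM in PBS to 29.4 ± 9.78 in TRT_ISV_DCP and 21.6 ± 13.6 in TRT_DCP. Per1 and Per2, also clock genes, fell in TRT_DCP against PBS (log2FC -2.01, SE 0.31, and -1.31, SE 0.35), while the clock activator Bmal1 had a log2FC of -0.02 (SE 0.17). Times of day of collection are not in the labels. These comparisons share the PBS libraries, so their values are not independent.

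Of the lists without a result so far, T cell inhibitory receptors were higher in TRT_ISV_DCP than in PBS (2 of 12 rose, Cd160 and Entpd1, 3 adjusted over the list alone, camera adjusted p = 0.00529, adjusted p = 0.318 with an estimated correlation), a call lost without PBS replicate 2 (0.0712). Regulatory T cell genes (median log2FC 0.69, camera adjusted p = 0.0943), lymphoid tissue chemokine genes (0.27, 0.523), suppressive myeloid genes (-0.17, 0.546), melanocyte genes (0.13, 0.366) and cornified epidermis genes (-0.60, 0.142) did not pass there. When adjusted over the list alone 1, 0, 0, 1 and 0 of their genes did. The suppressive myeloid list was lower in TRT_ISV_DCP than in ISV_DCP (median -0.61, 1 of 14 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.429 with an estimated correlation), a call lost without ISV_DCP replicate 1 (0.148) or TRT_ISV_DCP replicate 1 (0.0706). The p53 and DNA damage list was lower in TRT_ISV_DCP than in PBS (median -0.19, camera adjusted p = 0.0427, adjusted p = 0.318 with an estimated correlation; 6 lower and 1 higher adjusted over the list alone), with its call lost without PBS replicate 3 (0.145), TRT_ISV_DCP replicate 1 (0.0562) or replicate 2 (0.0863). The death receptor gene Fas, which interferon also induces, was its 1 gene that rose. The list's mean level lay between 4.19 and 4.76 log2 CPM in all 14 libraries.

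The first pattern weighed was the level of Pmel, under 1 CPM in all 14 libraries although the samples were labelled B78. Mitf and Pax3, also in the melanocyte list, averaged 12.6 and 10.8 CPM. B78 descends from the B16 melanoma, which lacks the Cdkn2a locus, so under that label only host cells could supply its transcripts. Cdkn2a lay over 5 CPM in 14 of 14 libraries (143 to 293 CPM, median 193), which argues against B78 cells as the bulk of these samples. The squamous MOC2 line of the design text stays open: Krt8 and Krt18 both lay over 50 CPM in 13 of 14 libraries, but other epithelia express them too, and the median of Krt5 was 0.00615 CPM and of Trp63 0.267 CPM. Reference profiles of either line were not available here.

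The second pattern was the number of genes called in the comparisons with TRT_DCP. For TRT_DCP against PBS, a bias of transcript length or GC content between libraries and skin cells in the keratin-rich library were each argued against as the whole cause, since 2967 and 3333 genes were called after the correction and without that library, beside 3123. Of the 3123 genes, 2445 were also called after the correction. Log2 fold change and length correlated here too (Spearman rho -0.224). Median lengths were 2539 nucleotides for genes that rose, 4422 for those that fell and 3282 for those not called. A partial contribution of length is therefore not excluded. A spread estimate made smaller by the other groups' libraries stays open. A fit of the 2 groups alone called 0 genes, the median SE of the called genes going from 0.226 to 0.276, but its residual degrees of freedom also went from 9 to 4, and the same fit left 7 of 727 and 0 of 606 genes in 2 other comparisons. For TRT_ISV_DCP against TRT_DCP, in contrast, a length or GC bias is a candidate cause, because 0 of 606 genes were called once the trend was removed, with the median absolute log2 fold change of those genes going from 0.737 to 0.388 and their median SE from 0.157 to 0.136. Log2 fold change and length correlated across genes there (Spearman rho 0.463; genes are not independent replicates), and a treatment effect on long genes, muscle genes among them, was not separated from a difference in RNA or library preparation.

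The third pattern was the higher interferon gamma list in TRT_ISV_DCP than in ISV_DCP. The list still passed without the library richest in muscle (camera adjusted p = 3.61e-25), but this decides nothing about muscle as the source, since the other 2 libraries, at 2.89 and 2.45 log2 CPM of muscle genes, also lay above the ISV_DCP libraries (at most 0.02). Interferon gamma levels did not follow muscle from library to library, at 4.63, 5.40 and 5.30 in TRT_ISV_DCP where muscle was 2.89, 5.77 and 2.45, and at 2.33 in PBS replicate 2 where muscle was 2.48, but each of these values is a single library and muscle is not excluded by them. More T cells and natural killer cells with the same response per cell may explain part of the difference, since the median log2 change kept 71.4% of its size with their level as a covariate (1.62 to 1.15) and the list still passed with 21 of 24 genes higher (camera adjusted p = 5.53e-15). The 71.4% lay above 2/3, the bound set in advance for a cause other than cell number. The 95% interval over list members, 54.4% to 86.9%, reaches below that bound. This interval was added after the result and drawn over genes that move together, so it does not measure the spread between libraries. More cells and a stronger response per cell, an untested hypothesis, therefore cannot be told apart in these 6 libraries.

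Other splits of the same 6 libraries were fitted for each comparison of 3 against 3, and 10 splits are too few for a share under 0.05. TRT_ISV_DCP against PBS gave 727 genes and at most 0 in another split (1 of 10 as large), TRT_DCP against PBS 3123 and at most 550 (1 of 10), and TRT_ISV_DCP against TRT_DCP 606 and at most 0 (1 of 10). In ISV_DCP against PBS and TRT_ISV_DCP against ISV_DCP the real split gave 0 genes, as did all 10. The split with 550 genes set PBS replicates 1 and 3 with TRT_DCP replicate 3 against the rest.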
